A study of Mus musculus with 167 samples.

How the data were processed

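Libraries of polyA RNA from mouse liver were analysed, 167 in 21 groups of genotype and age. Per the labels, the mice were of strain C57BL/6, tissue was flash frozen, RNA was extracted with a column kit and libraries were sequenced on Illumina HiSeq instruments. Per the labels' processing entries, base calling used CASAVA 1.8.2. The aligner, the quantifier, the genome build and the annotation release are not given in the sources used here.

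The authors deposited a table of expected counts per gene and a table of FPKM per gene, both with 39179 Ensembl gene IDs. In the deposited table of expected counts 14.1% of the values were not whole numbers, so they were rounded before the count models. Per the file headers each column of both tables is 1 library, and every column belonged to a library analysed here. Symbols, positions, GC content and length came from GENCODE M21 (GRCm38), in which 37607 IDs matched and 1572 did not. The total of the expected counts per library ran from 32025244 to 57151736. The SE of a fold change covers counting error and the spread between animals together.

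No library was left out of the main comparisons, and genes with too few counts for the filter were not tested. Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr on genotype and sex, the quasi-likelihood fit (glmQLFit) and its F test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. At each age all 7 genotypes were fitted together with sex, and each longer allele was contrasted with Q20, Q20 with the wild type, and females with males. The CAG slope was fitted in the 6 knock-in lines with sex, per 100 repeats, taking the repeat length from the name of the line. Interactions of the slope with sex and with age, and differences between ages with genotype and sex in the model, were fitted in the knock-in lines. The SE of a log2 fold change was its size divided by the square root of the F statistic. Group means in CPM use TMM-normalized library sizes.

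48 gene lists were tested with limma's camera (3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. For each list the members past the threshold were counted over all genes and with p-values adjusted over the list alone. The lists, the comparisons, a set of alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names, for the CAG slope, Q175 against Q20, Q20 against the wild type, sex and age, genes among the 10 with the largest positive and the 10 with the largest negative log2 fold change of those past the threshold with a mean log2 CPM of at least 1. For the other lines against Q20 it names genes among the 5 with the largest absolute log2 fold change. It names Htt everywhere, and in each list described up to 4 members past the threshold with the smallest p, or else 2 members with the smallest p. Genes outside the rule are named as chosen after their values were seen. Some genes that the rule gives are not reported here.

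These alternatives were DESeq2 1.42.0, RLE normalization, no low-count filter, limma on log2 FPKM with a pseudocount of 0.1, a fit of only the 2 groups compared, a block on the replicate number, each sex alone, the rank of the CAG length, the slope without the Q20 or the Q175 libraries, the index set as a covariate, windows of 5 and 20 Mb around Htt in place of 10 Mb, the Q80 library M5 left out, and each library of Q175 and Q20 left out in turn. Alternatives added after the data were seen left out libraries with muscle or blood RNA (Acta1 above 1 CPM or Hba-a1 above 1000 CPM at 10 months), with Krt19 above 10 CPM, the Q20 females F1, F3 and F4 of 6 months or the Q20 female F1 of 10 months, used robust dispersion estimates, or removed a trend on GC content and length (98.7% of the genes had both). Other splits of the samples were drawn with seed 1, 100 for the slope and 40 for the other comparisons.

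The count models were tested on simulated data with known changes. For Q175 against Q20 at 10 months edgeR recovered 36, 88, 90 and 100% of the genes changed by 1.25, 1.5, 2 and 4 fold, with 20 false calls among 177. Libraries were also checked for identical columns, of which there were 0, and for the sex of Xist and Y-linked genes, which matched the label in 55 of 56 libraries at 2 months, 56 of 56 at 6 months and 55 of 55 at 10 months.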

Results

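Messenger RNA was measured by sequencing in the livers of wild-type mice and of mice that carry a knock-in allele of Htt, the gene mutated in Huntington's disease, with CAG repeats of 6 lengths. The alleles are named by their repeat length (Q20, Q80, Q92, Q111, Q140 and Q175), and every knock-in animal was heterozygous. Livers were taken at 2, 6 and 10 months, which gave 21 groups of genotype and age with 8 libraries each, except Q80 at 10 months with 7. Groups held 4 females and 4 males, apart from Q80 at 2 months, labelled as 3 females and 5 males, and Q80 at 10 months, with 4 females and 3 males. The total count per library ran from 32025244 to 57151736 with a median of 38663519, and the median was 34696186 at 2 months, 46777190.5 at 6 months and 38228631 at 10 months. Log2 fold changes are given with their standard error (SE), group means in normalized CPM with the standard deviation (SD), and n = 8 per group unless another number is given. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test over all genes tested, unless another tool is named.

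Htt (ENSMUSG00000029104, GRCm38 chromosome 5, 34761740 to 34912534), which encodes huntingtin and was counted over both alleles together, fell with the length of the repeat at every age. At 2 months its mean was 29.3 ± 3.31 CPM (SD) in Q20 and 21.1 ± 3.13 CPM in Q175. The means at 6 months were 32.2 ± 2.76 and 21.3 ± 0.982 CPM, and at 10 months 29.1 ± 4.66 and 18.5 ± 4.04 CPM. The slope per 100 CAG repeats was −0.27 ± 0.04 on the log2 scale (SE) at 2 months (adjusted p = 0.000554), −0.39 ± 0.04 at 6 months (adjusted p = 1.43e-07) and −0.42 ± 0.05 at 10 months (adjusted p = 4.05e-07). Between Q175 and Q20 the log2 fold change was −0.48 ± 0.07, −0.58 ± 0.07 and −0.67 ± 0.10 at 2, 6 and 10 months (adjusted p = 0.000144, 1.41e-06 and 0.000124). At 6 months Htt was also below Q20 in Q80 (−0.21 ± 0.07), Q92 (−0.39 ± 0.07), Q111 (−0.32 ± 0.07) and Q140 (−0.56 ± 0.07), and at 10 months in Q111 (−0.44 ± 0.10, adjusted p = 0.00953). The calls of Htt in Q80 and Q111 ended at folds near these when only the 2 groups compared were fitted, with −0.21 in Q80 at 6 months (adjusted p = 0.0966) and −0.32 and −0.44 in Q111 at 6 and 10 months (adjusted p = 0.0791 and 0.152). Without the Q20 females F1, F3 and F4, chosen after the data were seen, Htt at 6 months had similar folds that did not pass, −0.23 ± 0.08 in Q80 (adjusted p = 0.212) and −0.33 ± 0.08 in Q111 (adjusted p = 0.24). Without the libraries with Krt19 above 10 CPM its fold in Q111 at 10 months was −0.45 ± 0.11 (adjusted p = 0.0987). Htt was lower in females than in males (−0.27 ± 0.04 at 2 months, −0.21 ± 0.04 at 6 months and −0.30 ± 0.05 at 10 months), but with limma on FPKM this sex difference did not pass at 6 and 10 months (−0.06 and −0.10, adjusted p = 0.214 and 0.157). The slope of Htt at 2 months did not pass without the Q175 libraries (−0.27, adjusted p = 0.191) or without the Q20 libraries (−0.19, adjusted p = 0.497), nor in females alone (−0.33, adjusted p = 0.0524) or males alone (−0.22, adjusted p = 0.106).

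**Figure D1:**
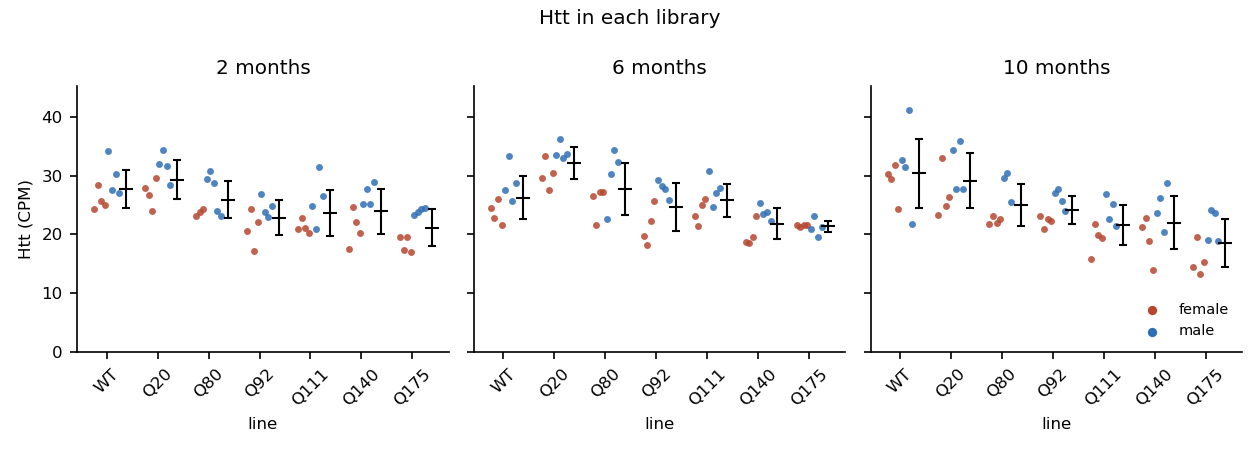
Htt in CPM (y axis) for each library (points, coloured by labelled sex) by genotype (x axis), with 1 panel per age and the group mean and SD as a bar beside the points. Group means were 29.3 CPM in Q20 and 21.1 CPM in Q175 at 2 months, 32.2 and 21.3 CPM at 6 months, and 29.1 and 18.5 CPM at 10 months.

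At 2 months few genes differed between Q175 and Q20. Lum (lumican, a proteoglycan of the collagen matrix; ENSMUSG00000036446, chromosome 10, 97565128 to 97572703) fell from 11.5 ± 2.43 CPM (SD) in Q20 to 7.43 ± 1.93 CPM in Q175, a log2 fold change of −0.64 ± 0.11 (SE, adjusted p = 0.00208). Gabra3, a subunit of GABA-A receptors (−0.92 ± 0.16), Col4a5, a basement membrane collagen chain (−0.97 ± 0.18), the glypican Gpc6 (−0.76 ± 0.18), the actin-severing protein Gsn (−0.58 ± 0.13) and the endothelin receptor Ednra (−0.54 ± 0.10) fell as well. Syvn1, a ubiquitin ligase of the endoplasmic reticulum (ER), rose by 0.87 ± 0.20 (adjusted p = 0.0306), with 105 ± 61.8 CPM in Q175 and 56 ± 13.6 CPM in Q20, and the Q175 male M1 stood at 244.6 CPM. The insulin-degrading protease Ide rose by 0.60 ± 0.14 and the glycosyltransferase Galnt11 by 0.56 ± 0.11. Fgf21, a hormone that the liver secretes in fasting and stress, rose by 2.09 ± 0.50 (adjusted p = 0.0403). The rule on fold changes, which asks for a mean log2 CPM of at least 1, does not give this gene. Across the allelic series, Gabra3 (slope −0.59 ± 0.09), Lum (−0.42 ± 0.07), Ednra (−0.35 ± 0.06) and Pdgfra, a growth factor receptor of mesenchymal cells (−0.34 ± 0.08, adjusted p = 0.0395), fell with repeat length. Fam25c (0.58 ± 0.13), the T cell kinase Zap70 (0.43 ± 0.10) and the replication nuclease Fen1 (0.25 ± 0.06) rose with it.

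Of the 19 measured markers of stellate cells and fibroblasts 2 fell in Q175 at 2 months, Lum and Dcn (decorin, −0.36 ± 0.08), and 9 were lower when adjusted over the list alone. The camera test placed this list below the other genes (adjusted p = 4.66e-07), and adjusted p = 0.188 with an estimated correlation. Along the series 3 of them fell (Lum, Dcn and Pdgfra) and 9 when adjusted over the list alone, with camera adjusted p = 1.87e-08, and adjusted p = 0.149 with an estimated correlation. Of 6 red cell genes 0 passed over all genes and 6 were higher when adjusted over the list alone (camera adjusted p = 3.18e-05, and adjusted p = 0.188 with an estimated correlation). Hba-a1 stood at 0.65 ± 0.22 and Hba-a2 at 0.61 ± 0.21, alpha globin genes so alike that their reads are hard to tell apart. Of 20 genes of the ER unfolded protein response 1 rose, Syvn1, and 5 when adjusted over the list alone (camera adjusted p = 6.21e-08, and adjusted p = 0.32 with an estimated correlation). Of 26 proteasome subunits 0 passed over all genes and 3 when adjusted over the list alone, with Psmd12 at 0.16 ± 0.05 (camera adjusted p = 9.26e-09, and adjusted p = 0.32 with an estimated correlation). Of 15 mismatch repair genes and other modifiers of CAG instability, 0 passed at 2 months.

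At 2 months 47 of 15137 genes differed between Q175 and Q20, 16 higher and 31 lower, and 41 of 15053 genes followed the repeat length, 13 upward and 28 downward. The count of 47 became 19 without the Q20 female F4, 20 without the Q175 male M1, 22, 25 and 31 without the Q20 males M2, M1 and M4, 26 without the Q175 female F1, 30 without the Q20 female F1, 71 without the Q20 female F3 and 77 without the Q175 female F2. DESeq2 gave 143 genes for Q175 against Q20 and 169 along the series, where females alone gave 1 and males alone 11. For Q92, Q111 and Q140 against Q20 edgeR called 0 genes each, and 1079, 903 and 2011 genes had an unadjusted p below 0.05. DESeq2 called 3, 0 and 24 genes in these comparisons, and limma on FPKM 0, 0 and 1.

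In Q80 at 2 months 15 genes were higher than in Q20 and 0 lower, and those with the largest fold changes are genes with higher levels in female than in male liver. They were the cytochromes P450 Cyp2b13 (6.90 ± 1.14, SE) and Cyp2a4 (6.47 ± 1.01) and the sulfotransferases Sult3a1 (6.25 ± 1.10), Sult2a1 (5.84 ± 1.06) and Sult2a2 (5.76 ± 1.01), families in which reads of close paralogs are hard to tell apart. These values are adjusted for the labelled sex. The mean of Cyp2b13 was 139 ± 161 CPM (SD) in Q80 and 148 ± 161 CPM in Q20. The Q80 library labelled male M5 had 314 CPM of Cyp2b13, against at most 0.476 CPM in the other 28 male libraries of this age. Its Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 0 CPM, against 132 to 172 CPM in those males. Xist, the RNA of the inactive X chromosome, stood at 0.507 CPM in it and at 393 to 731 CPM in the 27 female libraries. Its library name shares a code with the 3 Q80 females of this age that the other 4 Q80 males do not carry. Without M5, 2 genes passed.

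At 6 months the metallothionein genes Mt1 and Mt2 and most of the measured markers of macrophages and neutrophils were lower in Q175 than in Q20. Pnpla3, a lipase of lipid droplets (1.33 ± 0.39, SE), Ppp1r3b, a regulator of glycogen synthesis (0.89 ± 0.23), the acyl-CoA thioesterase Acot1 (1.11 ± 0.34) and the collagen gene Col27a1 (1.15 ± 0.27) rose. The metallothioneins Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568; −3.31 ± 0.71) and Mt1 (−2.36 ± 0.50) fell, Mt2 from 117 ± 129 to 11.7 ± 10.6 CPM (SD, adjusted p = 0.00259). The chemokine Cxcl13 (−1.94 ± 0.43), the cytokine Il1b (−1.56 ± 0.37) and asparagine synthetase Asns (−1.97 ± 0.54) fell. Along the series Mt2 (slope −2.20 ± 0.43), the acute phase gene Orm2 (−1.93 ± 0.59), the siderophore-binding protein Lcn2 (−2.31 ± 0.63), the integrin Itgam (−0.87 ± 0.15) and the macrophage receptor Adgre4 (−0.81 ± 0.15) fell. Itgam averaged 4.13 ± 3.03 CPM (SD) in Q20. In Q80, Q92, Q111, Q140 and Q175 it averaged 1.66 ± 0.27, 1.44 ± 0.31, 1.89 ± 0.40, 1.70 ± 0.34 and 1.44 ± 0.66 CPM. Its fall thus lay between Q20 and the longer alleles, with no steady fall among these.

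Of 17 measured markers of Kupffer cells and macrophages, 15 fell in Q175 at 6 months, 0 rose, and 17 were lower when adjusted over the list alone. The camera adjusted p was 5.86e-14, and adjusted p = 0.498 with an estimated correlation. Among them were the lysozyme Lyz2 (−0.95 ± 0.21), the growth factor receptor Csf1r (−1.06 ± 0.24), Adgre1, which encodes F4/80 (−1.27 ± 0.29), and Timd4 (−1.15 ± 0.26). The mean log2 level of the list lay 1.42, 1.20 and 1.16 above the median library of the age in the Q20 females F4, F3 and F1, and at −1.60 and −1.11 in the Q175 males M4 and M3. Of 8 neutrophil genes 6 fell, and 8 when adjusted over the list alone, among them the metalloprotease Mmp9 (−1.02 ± 0.26) and Ngp (−2.61 ± 0.68), with camera adjusted p = 8.24e-06, and adjusted p = 0.498 with an estimated correlation. Of 16 sinusoidal endothelial markers 4 fell, and 7 when adjusted over the list alone, including the cadherin Cdh5 (−0.85 ± 0.22) and the mannose receptor Mrc1 (−0.89 ± 0.24). For these camera gave adjusted p = 8.24e-06, and adjusted p = 0.62 with an estimated correlation. Of 24 interferon response genes 5 fell, and 8 when adjusted over the list alone, with Ifit2 at −0.84 ± 0.18 and Oasl2 at −0.64 ± 0.15 (camera adjusted p = 0.0003, and adjusted p = 0.584 with an estimated correlation). Of 20 stellate cell and fibroblast markers 5 fell, and 8 when adjusted over the list alone, with Col4a1 at −0.64 ± 0.16 (camera adjusted p = 4.22e-05, and adjusted p = 0.544 with an estimated correlation).

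Some subunits of the proteasome and of oxidative phosphorylation and some genes of fat synthesis rose in Q175 at 6 months. Of 26 proteasome subunits 9 rose, 0 fell, and 17 were higher when adjusted over the list alone, with Psma2 at 0.23 ± 0.05 and Psmb3 at 0.24 ± 0.06. The camera adjusted p was 1.81e-10, and adjusted p = 0.544 with an estimated correlation. Of 29 nuclear genes of oxidative phosphorylation 3 rose, among them Cyc1 (0.18 ± 0.05), and 13 when adjusted over the list alone (camera adjusted p = 1.33e-07, and adjusted p = 0.584 with an estimated correlation). Of 20 genes of fatty acid and triglyceride synthesis 3 rose, and 3 when adjusted over the list alone: Mlxipl, which encodes the carbohydrate-responsive factor ChREBP (0.40 ± 0.11), malic enzyme Me1 (0.66 ± 0.19) and Pnpla3. Camera gave adjusted p = 0.00103 for them, and adjusted p = 0.544 with an estimated correlation. Of 18 genes of the urea cycle and amino acid breakdown 4 fell along the series, and 7 when adjusted over the list alone, with Cps1 at −0.24 ± 0.07 (camera adjusted p = 0.000557, and adjusted p = 0.644 with an estimated correlation). Of 15 mismatch repair genes and other modifiers of CAG instability 1 rose with repeat length, Msh6 (0.16 ± 0.04, adjusted p = 0.00899), and 0 fell.

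Over all genes, 1699 of 15640 passed between Q175 and Q20 at 6 months, 690 higher and 1009 lower, and 972 of 15498 followed the repeat length, 383 upward and 589 downward. Without the Q20 females F1, F3 and F4, chosen after their marker levels were seen, 13 genes passed for Q175 against Q20 and 21 along the series. Mt2 (−3.34 ± 0.77, adjusted p = 0.0575), Mt1 (−2.35 ± 0.56, adjusted p = 0.0575) and Asns (−2.07 ± 0.57, adjusted p = 0.0922) then did not pass. Ppp1r3b (0.86 ± 0.27, adjusted p = 0.14), Pnpla3 (1.57 ± 0.54, adjusted p = 0.173) and Col27a1 (0.97 ± 0.32, adjusted p = 0.156) did not either. These 6 folds lay within 1 SE of those with the 3 females. Cxcl13 (−0.77 ± 0.42, adjusted p = 0.389), Il1b (−1.04 ± 0.41, adjusted p = 0.229) and Acot1 (0.76 ± 0.38, adjusted p = 0.35) did not pass and lay nearer 0. Htt still passed (−0.59 ± 0.08, adjusted p = 8.25e-05). Along the series Mt2 (−2.20 ± 0.52, adjusted p = 0.0602) and Orm2 (−1.72 ± 0.80, adjusted p = 0.372) did not pass, within 1 SE of their slopes with the 3 females. Itgam (−0.30 ± 0.12, adjusted p = 0.266), Adgre4 (−0.45 ± 0.16, adjusted p = 0.198) and Lcn2 (−1.33 ± 0.97, adjusted p = 0.609) did not pass and lay nearer 0. Single libraries moved the count of 1699 to 987 (without the Q20 female F1), 1108 (Q20 F3), 1080 (Q175 male M3) and 1027 (Q175 M4).

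The other lines also differed from Q20 at 6 months. Mt2 fell in Q92 (−2.02 ± 0.66, SE), Q111 (−2.87 ± 0.69) and Q140 (−2.08 ± 0.66), and in Q111 Mt1 (−2.12 ± 0.49) and Cxcl13 (−1.55 ± 0.42) fell with it. In Q80 the endothelial hyaluronan receptor Lyve1 (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239) fell (−1.41 ± 0.37, adjusted p = 0.0139). In Q111 the male-biased fatty acid hydroxylase Cyp4a12a rose by 1.38 ± 0.33. The mucosal gene Dmbt1 had 82.4 ± 233 CPM (SD) in Q111 and levels near 0 in Q20, in a group whose female F1 carried 36.6 CPM of the bile duct keratin Krt19. Q80 gave 1455 genes (583 higher, 872 lower), Q92 2814 (1105 higher, 1709 lower), Q111 194 (85 higher, 109 lower) and Q140 936 (421 higher, 515 lower). Without the Q20 females F1, F3 and F4 these counts were 149, 505, 1 and 167. Mt2 did not pass then in Q92 (−2.05 ± 0.76, adjusted p = 0.118), Q111 (−2.90 ± 0.77, adjusted p = 0.31) or Q140 (−2.12 ± 0.75, adjusted p = 0.185). Nor did Mt1 (−2.09 ± 0.56, adjusted p = 0.328) and Cyp4a12a (1.23 ± 0.36, adjusted p = 0.356) in Q111 or Lyve1 (−1.36 ± 0.43, adjusted p = 0.126) in Q80. These 6 folds lay within 1 SE of those with the 3 females. Cxcl13 in Q111 did not pass and lay nearer 0 (−0.41 ± 0.41, adjusted p = 0.866). Without the Q111 female F1 this line gave 85 genes. Cyp4a12a (0.83 ± 0.25, adjusted p = 0.0856) then did not pass and lay nearer 0. Cxcl13 (−1.41 ± 0.43, adjusted p = 0.0929) did not pass either, within 1 SE of its fold with this female.

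**Figure D2:**
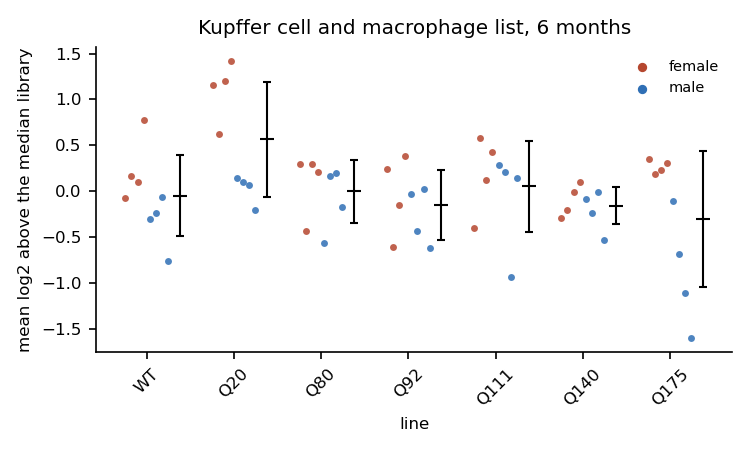
Mean log2 level of the Kupffer cell and macrophage markers above the median library at 6 months (y axis) in each library (points, coloured by labelled sex) by genotype (x axis), with the group mean and SD as a bar beside the points. The Q20 females F4, F3 and F1 stand at 1.42, 1.20 and 1.16 and the Q175 males M4 and M3 at −1.60 and −1.11.

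At 10 months skeletal muscle genes had large rises in Q175, with very high levels in the females F3 and F4, and Ces3b, Sult5a1 and Odc1 fell. The sarcomere gene Ttn (ENSMUSG00000051747, chromosome 2, 76703980 to 76982547) rose by 7.06 ± 1.25 (SE, adjusted p = 0.001) and Tcap, which binds it, by 7.88 ± 1.33. The Q175 female F3 carried 174 CPM of Ttn and 273 CPM of skeletal actin Acta1, and the female F4 7.89 CPM of Acta1. Hba-a1 rose by 3.29 ± 0.67, with 3469 CPM in the male M4, and Nrgn, a neuronal protein also found in platelets, by 5.14 ± 0.96. The immunoglobulin gene Ighg1 rose by 4.30 ± 1.02 and the early response gene Nr4a1 by 3.58 ± 0.80. The carboxylesterase Ces3b (ENSMUSG00000062181, chromosome 8, 105083753 to 105093929) fell from 426 ± 228 CPM (SD) in Q20 to 258 ± 136 CPM in Q175 (log2 fold change −0.71 ± 0.14, adjusted p = 0.00172). The sulfotransferase Sult5a1 (−1.35 ± 0.31) and ornithine decarboxylase Odc1, an enzyme of polyamine synthesis (−0.49 ± 0.12), fell as well. Along the series Ces3b (−0.41 ± 0.09), Sult5a1 (−0.77 ± 0.19), Fam126a (−0.23 ± 0.06) and Sepsecs, an enzyme of selenocysteine synthesis (−0.17 ± 0.04), fell with repeat length, and the stress-induced factor Atf3 (1.69 ± 0.37) and Ttn (7.57 ± 0.94) rose.

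Of 6 measured skeletal muscle genes 6 rose in Q175 at 10 months, and 6 when adjusted over the list alone, among them Mylpf (3.59 ± 0.66), with camera adjusted p = 1.52e-05, and adjusted p = 0.513 with an estimated correlation. The list mean lay 6.61 above the median library of the age in the female F3 and 2.27 above it in F4. Of 11 adipocyte genes 5 rose, and 8 when adjusted over the list alone, with lipoprotein lipase Lpl at 1.36 ± 0.30 and the fatty acid carrier Fabp4 at 1.39 ± 0.32 (camera adjusted p = 0.000366, and adjusted p = 0.513 with an estimated correlation). The adipocyte list mean was 1.98 above the median in F4. Of 7 red cell genes 1 rose, Hba-a1, and 4 when adjusted over the list alone (camera adjusted p = 0.0928). Of 12 B and plasma cell genes 0 passed and 1 when adjusted over the list alone (camera adjusted p = 0.104), and the list mean lay 1.74 above the median in the Q175 female F1. Of 18 immediate early genes 3 rose, Atf3 (2.60 ± 0.54), Fosb (3.85 ± 0.82) and Nr4a1, and 11 when adjusted over the list alone (camera adjusted p = 2.11e-05, and adjusted p = 0.513 with an estimated correlation). The mean of this list stood 2.52 above the median in F3. Of 20 major urinary protein genes, pheromone carriers whose reads are hard to tell apart, 1 fell, Mup5 (−2.21 ± 0.46), and 7 when adjusted over the list alone (camera adjusted p = 0.000321, and adjusted p = 0.513 with an estimated correlation). Of 17 Kupffer cell and macrophage markers 0 rose and 0 fell at this age.

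At 10 months 197 of 15689 genes passed between Q175 and Q20, 145 higher and 52 lower, and 93 of 15629 followed the repeat length, 79 upward and 14 downward. Without the Q175 libraries with muscle or blood RNA (F3, F4 and M4), chosen after their levels were seen, 3 and 9 genes passed, and Ttn, Nrgn and Hba-a1 stood below Q20 (−0.24, −0.20 and −0.13). Htt still passed then (−0.58, adjusted p = 0.0272) and so did Ighg1 (5.02, adjusted p = 0.0272), but Ces3b (−0.68, adjusted p = 0.112), Sult5a1 (−1.50, adjusted p = 0.147), Odc1 (−0.48, adjusted p = 0.287) and Nr4a1 (0.95, adjusted p = 0.755) did not. Along the series Htt still passed (−0.38, adjusted p = 7.17e-05), while Atf3 (0.22, adjusted p = 0.995), Ttn (−0.32, adjusted p = 0.995), Ces3b (−0.34, adjusted p = 0.492), Sult5a1 (−0.76, adjusted p = 0.439), Fam126a (−0.20, adjusted p = 0.652) and Sepsecs (−0.15, adjusted p = 0.717) did not. The count of 197 was 51 without F3 alone, 102 without the Q20 male M3, 128 without M4 and 365 without the Q175 female F2. With limma on FPKM 0 genes passed, and when only Q175 and Q20 were fitted 0 passed in edgeR, against 2134 with an unadjusted p below 0.05 in the fit of all groups and 212 called by DESeq2. Without the Q175 libraries 3 genes followed the repeat length, and without the Q20 libraries 723, of which 309 went upward and 414 downward.

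In Q92 at 10 months the early response factor Egr1 rose by 3.21 ± 0.76 (SE), the insulin-suppressed binding protein Igfbp1 by 3.27 ± 0.80 and Ppp1r3g, a glycogen-targeting phosphatase subunit, by 3.84 ± 1.05. In Q111 the keratin Krt19 rose by 3.66 ± 0.74, the mucin Muc1 by 4.05 ± 0.77, the smooth muscle actin Acta2 by 2.81 ± 0.66 and Cd24a by 2.79 ± 0.61. Krt19 stood at 64.5 CPM in the Q111 male M3 and 10.8 CPM in the female F4, and at 21.8 and 16.3 CPM in the Q92 females F4 and F3. In Q80 (n = 7) Angptl4, a secreted inhibitor of lipoprotein lipase (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830), rose by 1.19 ± 0.21 (adjusted p = 0.0105), from 51.4 ± 8.07 to 118 ± 36.7 CPM (SD). The counts were 2 genes for Q80, 627 for Q92 (317 higher, 310 lower), 174 for Q111 (161 higher, 13 lower) and 1 for Q140. The immunoglobulin segment Igkv4-59, named after its value was seen, was the other gene of Q80 (−3.86 ± 0.74) and the gene of Q140 (−4.66 ± 0.78). Without the Q20 female F1, left out after its level was seen, Angptl4 alone passed in Q80 and 0 genes in Q140 in edgeR, where 624 had an unadjusted p below 0.05 with it and DESeq2 called 10. Without the libraries above 10 CPM of Krt19, a rule set after these levels were seen, 8 genes passed in Q111 and 18 in Q92. In Q92 Egr1 (3.49 ± 0.78, adjusted p = 0.0468) then still passed. Igfbp1 (3.40 ± 0.88, adjusted p = 0.0727) and Ppp1r3g (4.24 ± 1.08, adjusted p = 0.0702) did not, though their folds were no smaller. In Q111 Krt19 (1.38 ± 0.43, adjusted p = 0.328) and Muc1 (1.69 ± 0.42, adjusted p = 0.124) did not pass, at smaller folds. The same held for Acta2 (1.66 ± 0.51, adjusted p = 0.289) and Cd24a (0.55 ± 0.30, adjusted p = 0.63).

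**Figure D3:**
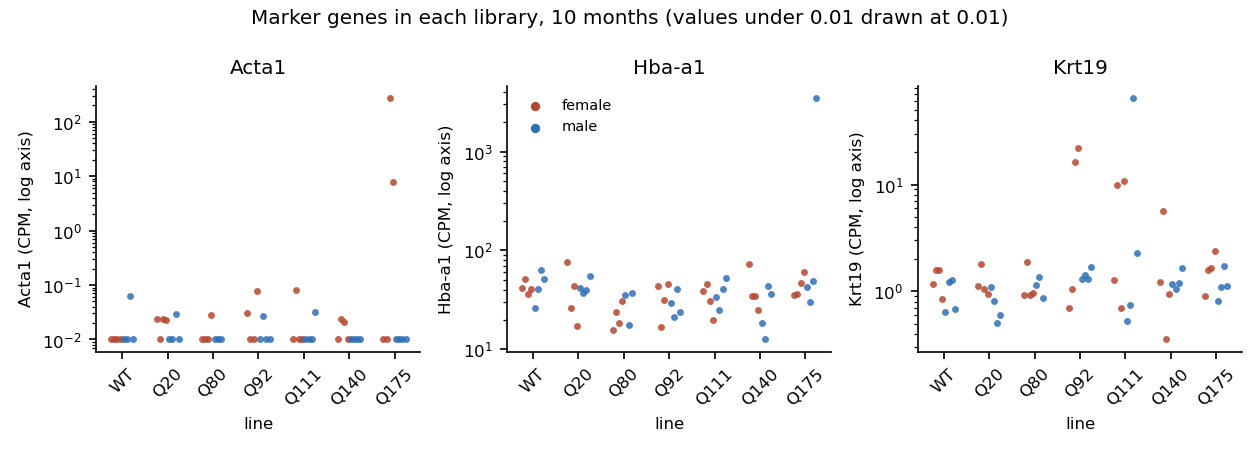
Acta1, Hba-a1 and Krt19, marker genes of skeletal muscle, red cells and bile duct epithelium, in CPM on a log axis (y) in each library (points, coloured by labelled sex) of 10 months by genotype (x). The Q175 female F3 stands at 273 CPM of Acta1, the Q175 male M4 at 3469 CPM of Hba-a1 and the Q111 male M3 at 64.5 CPM of Krt19.

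The comparison of Q20 with the wild type asks what the knock-in allele does with a short repeat. Abhd1 (ENSMUSG00000006638, chromosome 5, 30950066 to 30955091), a gene of an alpha/beta hydrolase on the chromosome of Htt, stood above the wild type in Q20 by 3.08 ± 0.40 at 6 months (SE, adjusted p = 7.61e-08) and by 2.39 ± 0.41 at 10 months (adjusted p = 0.00753), and its value at 2 months was 2.13 ± 0.47 (adjusted p = 0.242). Its mean at 6 months was 14.8 ± 8.14 CPM (SD) in Q20 and 1.72 ± 0.388 CPM in the wild type. Abhd1 reached 5 CPM in 132 of 143 knock-in libraries of all lines and in 2 of 24 wild-type libraries. At 10 months 2 genes passed, Abhd1 and Igkv4-59, the latter named after its value was seen. Without the Q20 female F1 Abhd1 alone passed (adjusted p = 0.0188), and when only the 2 groups were fitted Abhd1 did not pass (2.55, adjusted p = 1) and edgeR called 0 genes, against 363 with an unadjusted p below 0.05 in the fit of all groups and 5 called by DESeq2. At 2 months edgeR called 0 genes, 500 had an unadjusted p below 0.05, and DESeq2 called 1 and limma on FPKM 0. Of 24 acute phase genes 0 passed at 2 months and 4 were higher when adjusted over the list alone, with Saa2 at 4.94 ± 1.06 and Saa1 at 3.97 ± 0.91, close paralogs (camera adjusted p = 9.79e-05, and adjusted p = 0.959 with an estimated correlation). At 6 months 35 of 138 genes within 10 Mb of Htt passed between Q20 and the wild type, 25.4% against 32.3% elsewhere (Fisher's exact test, adjusted p = 0.446). At 10 months Abhd1 was the 1 gene of 139 near Htt that passed, against 1 elsewhere (Fisher's exact test, p = 0.0179, adjusted p = 0.161), too few calls to decide.

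At 6 months Q20 and the wild type differed in 5031 genes, 2794 higher and 2237 lower in Q20 (2562 and 2571 with RLE normalization, 2567 and 2568 in DESeq2, 3784 and 1092 with limma on FPKM), and the wild-type libraries of this age carry library names of another scheme than all knock-in libraries of the age, so that genotype and library batch cannot be told apart. Rn7s1 (−3.47 ± 0.54, SE) and Rn7s2 (−3.68 ± 0.54), genes of signal recognition particle RNA, and Gm42418 (−2.46 ± 0.42), a gene model that overlaps ribosomal RNA, were lower in Q20, the last with 1154 ± 1254 CPM (SD) against 6432 ± 3802 CPM. The acute phase genes Saa3 (−3.81 ± 0.92), Saa1 (−3.29 ± 1.18) and Saa2 (−3.36 ± 1.33) were lower, and Lyve1 (1.73 ± 0.38) and Mt2 (1.73 ± 0.66) higher. Of 13 transcripts of the mitochondrial genome 12 fell, and 13 when adjusted over the list alone, with mt-Nd3 at −1.18 ± 0.10 (camera adjusted p = 2.42e-12, and adjusted p = 0.713 with an estimated correlation). Of 26 proteasome subunits 21 fell and 1 rose, and 21 and 1 when adjusted over the list alone (camera adjusted p = 1.04e-10, and adjusted p = 0.807 with an estimated correlation). Of 16 sinusoidal endothelial markers 11 rose, and 16 when adjusted over the list alone, with Stab1 at 1.03 ± 0.16 (camera adjusted p = 7.29e-06, and adjusted p = 0.865 with an estimated correlation). Of 17 Kupffer cell and macrophage markers 11 rose, and 12 when adjusted over the list alone, with Csf1r at 1.11 ± 0.24 (camera adjusted p = 0.000758, and adjusted p = 0.939 with an estimated correlation), in a comparison whose Q20 females F4, F3 and F1 had list means 1.42, 1.20 and 1.16 above the median library. The log2 level of each gene was also taken relative to its mean over all libraries of this age. The rank correlation of these deviations with GC content, across genes within each library, averaged −0.342 ± 0.0852 (SD) in the wild type. In the knock-in groups of this age it averaged 0.00271 to 0.132. With a trend on GC content and length removed, chosen after this was seen, 2583 genes passed, and Htt went from 0.30 ± 0.07 (adjusted p = 0.00114) to 0.03 (adjusted p = 0.785).

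**Figure D4:**
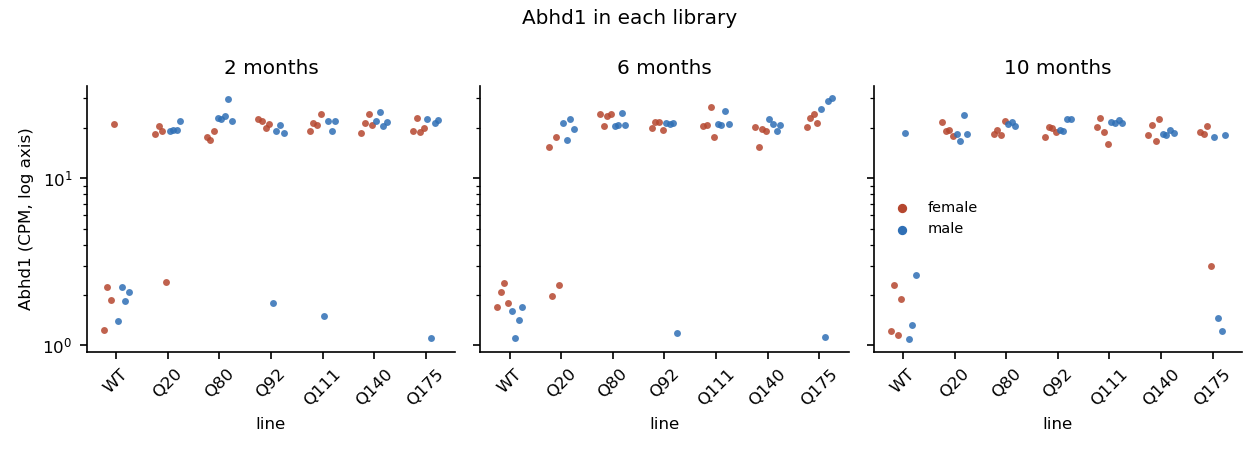
Abhd1 in CPM on a log axis (y) in each library (points, coloured by labelled sex) by genotype (x), with 1 panel per age. Of the knock-in libraries 132 of 143 stand at or above 5 CPM, and of the wild-type libraries 2 of 24.

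More genes passed for sex than for any comparison of lines: 8714 genes at 2 months, 9529 at 6 months and 8970 at 10 months differed between 27, 28 and 28 females and 29, 28 and 27 males. The line comparisons held 7 or 8 libraries per group, so these counts do not compare the sizes of the effects. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254) was higher in females by 10.15 ± 0.11, 10.01 ± 0.18 and 10.44 ± 0.14 (SE) at the 3 ages. In males the fatty acid hydroxylase Cyp4a12a was higher, with female against male values of −9.29 ± 0.35, −9.82 ± 0.22 and −9.54 ± 0.23, and so was the steroid enzyme Hsd3b5 (−7.37 ± 0.30, −8.43 ± 0.22 and −9.29 ± 0.16). Of 27 female-biased liver genes of a fixed list 27, 27 and 27 were higher in females, and 27, 27 and 27 when adjusted over the list alone. Of 24 male-biased genes 24, 24 and 24 were lower, and 24, 24 and 24 when adjusted over the list alone. With an estimated correlation the camera adjusted p of the female-biased genes was 0.0203, 3.11e-08 and 3.47e-05, and that of the male-biased genes 0.026, 4.27e-07 and 5.24e-06. The Q80 library M5 of 2 months counted as male, as labelled. At 2 and 10 months a code in the library names goes with sex in each line, M5 aside, and what it stands for is not given. An effect that goes with this code was not separated from sex.

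Genes of T and NK cells were higher in female liver, 18 of 19 at 2 months, 19 of 20 at 6 months and 18 of 20 at 10 months, and 18, 19 and 19 when adjusted over the list alone. The granzyme Gzmb stood at 1.34 ± 0.14, 1.28 ± 0.16 and 1.53 ± 0.17 (SE), and Cd4 went the other way (−1.38 ± 0.12 at 6 months). The camera adjusted p of this list was 1.36e-06, 2.39e-05 and 5.04e-06, and adjusted p = 0.151, 0.518 and 0.554 with an estimated correlation. Of 24 interferon response genes 17, 18 and 19 were higher in females, and 18, 19 and 19 when adjusted over the list alone, with the guanylate-binding protein Gbp3 at 1.52 ± 0.11, 1.86 ± 0.09 and 1.84 ± 0.08. For them camera gave adjusted p = 4.97e-05, 2.56e-06 and 6.28e-07, and adjusted p = 0.612, 0.49 and 0.554 with an estimated correlation. Of 26 proteasome subunits 26, 26 and 23 were lower in females, and 26, 26 and 24 when adjusted over the list alone, with Psmd11 at −0.47 ± 0.03, −0.56 ± 0.04 and −0.46 ± 0.03. Their camera adjusted p was 4.49e-13, 1.38e-11 and 4.38e-10, and adjusted p = 0.278, 0.49 and 0.554 with an estimated correlation. Of 20 genes of the ER unfolded protein response 13, 17 and 17 were lower, and 14, 17 and 18 when adjusted over the list alone, among them the ER chaperone Calr (−0.49 ± 0.06, −0.67 ± 0.07 and −0.56 ± 0.07). The camera adjusted p was 0.00222, 2.39e-05 and 2.31e-05, and adjusted p = 0.637, 0.597 and 0.746 with an estimated correlation.

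Whether the slope on repeat length differed between females and males was tested by an interaction. At 6 months 35 genes passed, 22 with a higher slope in females and 13 with a lower one, and DESeq2 called 172. The water channel Aqp8 (−1.40 ± 0.26, SE) had a lower slope in females and the cyclin Ccnd1 (1.35 ± 0.28) a higher one, both named after their values were seen. At 10 months 27 genes passed, 17 higher and 10 lower, and DESeq2 called 132. At 2 months edgeR and DESeq2 called 0 genes, and 803 had an unadjusted p below 0.05 in edgeR.

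With age, the antibody genes Ighg1, Igkc, Jchain and Ighm rose in the knock-in lines (48 libraries at 2 months, 48 at 6 and 47 at 10). No gene list was tested across ages. From 2 to 10 months the heavy chain gene Ighg1 rose by 4.54 ± 0.45 (SE), the light chain gene Igkc by 3.55 ± 0.25, Jchain, which joins secreted antibodies, by 3.06 ± 0.23 and Ighm by 2.53 ± 0.24, the last from 6.24 ± 2.38 to 47.5 ± 109 CPM (SD). The mean of the B and plasma cell list lay 2.04, 1.74 and 1.30 above the median library of 10 months in the Q80 female F4, the Q175 female F1 and the Q20 female F1. From 2 to 6 months Ighg1 rose by 2.95 ± 0.46 and Igkc by 1.75 ± 0.25. The chitinase-like gene Chil4 had 0.0471 ± 0.231 CPM at 2 months and 8.74 ± 28.3 CPM at 10 months. Slco1a1, an organic anion transporter, fell from 2 to 10 months (−1.57 ± 0.24, adjusted p = 6.69e-08). From 2 to 6 months Rn7s1 (−5.94 ± 0.24), Rn7s2 (−5.91 ± 0.23), the RNase P RNA gene Rpph1 (−4.82 ± 0.23) and Rn7sk (−3.21 ± 0.19) fell, Rn7s1 from 128 ± 63.4 to 2.37 ± 5.27 CPM. In all 8323 genes differed between 6 and 2 months (4196 higher, 4127 lower) and 3282 between 10 and 2 months (1835 higher, 1447 lower), of 15274 tested. The 6-month libraries of these lines carry names of another scheme than those of 2 and 10 months, so that age and library batch cannot be told apart in comparisons with 6 months. The libraries of 2 and 10 months share a scheme but carry serial numbers in separate ranges, so batch stays open between these ages as well. The slope on repeat length differed between 6 and 2 months for 32 genes, between 10 and 2 months for 102 and between 10 and 6 months for 579.

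**Figure D5:**
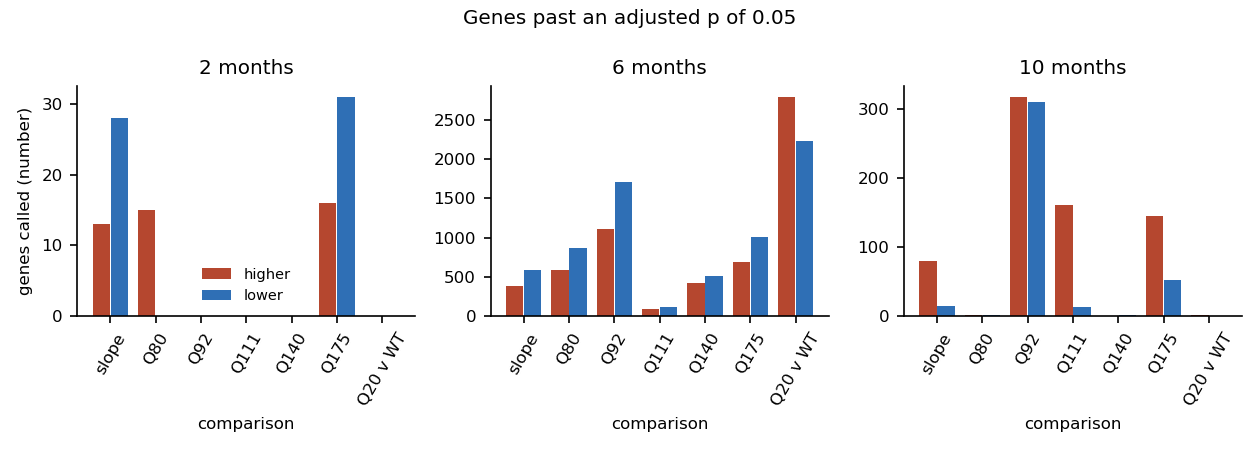
Number of genes past an adjusted p of 0.05 (y axis, with its own scale in each panel) for the slope on repeat length, each line against Q20 and Q20 against the wild type (x axis) at 2, 6 and 10 months (panels), higher and lower genes as separate bars. The counts for Q175 against Q20, higher and lower together, were 47, 1699 and 197 at the 3 ages.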

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

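The 8 tests that weigh explanations below, and their bounds, were chosen after the results were seen, and the tests on other splits of the samples before. In the third pattern the libraries left out were also picked after their marker levels were seen, and the bound for the index sets was widened to the counts without them after both counts were known.

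The genes called higher in Q80 than in Q20 at 2 months rest on the library labelled male M5, in which the mean log2 CPM of the female-biased genes was 6.12, just below the 27 females (at least 6.21) and above the 28 other males (at most 2.00), and whose name shares a code with the 3 Q80 females of this age that the other 4 Q80 males do not carry. An ordinary female library with a male label is argued against by 0.507 CPM of Xist, since the 27 female libraries had at least 393 CPM. A mixture of male and female RNA is argued against by the sum of the Y-linked genes, 0 CPM, where the 28 other males had at least 132 CPM. An animal with a single X chromosome and no Y chromosome may be a candidate explanation: the mean log2 CPM of 4 X-linked genes that escape inactivation was 6.00, inside the male range of 5.72 to 6.19 and below the female minimum of 6.23; an effect of the Q80 allele was not tested.

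Abhd1 stood at 5 CPM or more in 132 of 143 knock-in libraries and in 2 of 24 wild-type libraries. The length of the CAG repeat is argued against as the cause by 21 of 24 Q20 libraries at 5 CPM or more, the line with the shortest repeat. This count replaced a test on the slope of Abhd1, whose smallest adjusted p over the 3 ages was 0.443, after both values were known. A difference between haplotypes near Htt that came with the targeted allele may explain the pattern, as a hypothesis: of the 20 genes most correlated with Abhd1 across the knock-in libraries 4 lie within 10 Mb of it, where 0.22 are expected by chance (Fisher's exact test, p = 6.3e-05). An effect of the short-repeat knock-in allele itself had no test of its own. Values read afterward argue against it for the libraries they cover. Below 5 CPM stood 11 knock-in libraries. Among them the Q20 females F4 of 2 months and F2 and F4 of 6 months had 2.378, 1.983 and 2.291 CPM, where wild-type libraries below 5 CPM reached 2.625 CPM. The wild-type female F4 of 2 months and male M1 of 10 months stood at 20.99 and 18.6 CPM. Wrong genotype labels were not tested.

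Over the 15 pairs of lines the median number of genes called was 648 at 6 months, against 7 at 2 months and 166 at 10 months (399.5, 9.5 and 157.5 over the 10 pairs without Q20), though 3 pairs gave more at 10 months (Q92 and Q175 1862 against 658, Q111 and Q175 922 against 9, Q80 and Q111 220 against 56). Depth was not tested as a cause. The median total count was 34696186, 46777190.5 and 38228631 at 2, 6 and 10 months. At 6 months the Q92 libraries (49783732 to 57006607) were all deeper than those of Q20 (40154279 to 48184590). Those of Q80 (40324530 to 48242421) overlapped Q20, against which 1455 genes were called. Names of the 6-month libraries number Q175, Q111, Q20 and Q80 in separate ranges, which was not separated from line. Sets of sequencing indexes stay open: the 3 pairs that share a set gave 2814 (Q92 and Q20), 366 and 355 genes at 6 months and the 12 others a median of 653, but without the Q20 females F1, F3 and F4 the 2814 fell to 505 and the median of the 12 to 233.5 (highest 1337), and the set as a covariate, fitted without 2 Q175 libraries, took the slope from 972 genes to 428. CAG length cannot be told apart from chance over the 15 pairs, with a Spearman rho of 0.23 between the number of genes and the difference in length (exact permutation test over 720 orders, one-sided p = 0.308), and only 6 lines keep it open. For the pairs with Q20 (median 1455), macrophage-rich Q20 libraries may account for part of it, as a hypothesis: without the Q20 females F1, F3 and F4 the count for Q175 against Q20 was 13, rank 1 from the lowest of the 56 sets of 3 Q20 libraries left out, the others giving 110 to 2418. Lost calls do not by themselves place a fold in these females. Without them Mt2, Mt1, Asns, Ppp1r3b, Pnpla3 and Col27a1 lost their calls at folds within 1 SE of the full fit, while Cxcl13, Il1b and Acot1 lay nearer 0. In these females Clec4f stood at 181, 212 and 220 CPM and Cd5l at 183, 194 and 215 CPM, against medians of 84.2 and 84.5 CPM in the other 53 libraries, and 0 of the 18 listed markers are in another list, but F1 and F3 also stood 1.05 and 1.02 above the median on the acute phase list and the Q20 group 0.478 above it for neutrophils and 0.391 for sinusoidal endothelium, so that this set does not isolate macrophage content, and these libraries are in none of the 10 pairs without Q20, where the cause stays open.

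Htt and the total count in each group, and a few other genes in groups whose means are printed, gave 54 sets of values. Of these 3 held 1 library far from the rest, and chance alone gives about 1 in 20. They were Syvn1 in Q175 at 2 months, with 244.6 CPM in the male M1 and 134.8 CPM in the next library, the total count of the Q20 female F1 at 2 months (42472117) and that of the wild-type female F1 at 2 months (40556692). Acta1, Hba-a1 and Krt19 were not examined in this way, so the count leaves out the libraries that stood far out on these genes.

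The slope on repeat length differed between the sexes for 35 genes at 6 months and 27 at 10 months. Chance can be excluded at 6 months, where the highest of the other splits gave 5 genes. But outlying libraries of this age differ by sex at both ends of the slope. The mean of the macrophage list stood at 1.16, 1.20 and 1.42 in the Q20 females F1, F3 and F4, and at −1.11 and −1.60 in the Q175 males M3 and M4. The interaction was not fitted without them. Chance cannot be excluded at 10 months, where 6 of 40 splits gave as many. There the highest gave 268 genes, several times the real count, which may point to a structure of the samples that was not tested. The largest difference at 10 months by adjusted p, named after its value was seen, was that of Lmod2, a muscle gene (9.66 ± 1.45, SE), and the Q175 female F3 of that age carried 273 CPM of skeletal actin Acta1.

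The slope differed between 6 and 2 months for 32 genes, between 10 and 2 months for 102 and between 10 and 6 months for 579. Chance can be excluded for the 102, where the highest of the other splits gave 59, but not for the 32 (66) or the 579 (606). For the 32 and the 579, age and library batch cannot be told apart, because the 6-month knock-in libraries carry names of another scheme than those of 2 and 10 months. For the 102 batch stays open too, since the libraries of 2 and 10 months carry serial numbers in separate ranges. Genes among the 8 with the smallest p of each comparison, named after their values were seen, included Smim1 between 6 and 2 months (0.729 ± 0.116, SE) and the muscle genes Mylpf between 10 and 2 months (2.71 ± 0.481) and Casq1 between 10 and 6 months (2.53 ± 0.432).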

How the results depend on the processing

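Alternatives that left out the Q20 females F1, F3 and F4, libraries with muscle, blood or Krt19 RNA or the Q20 female F1 of 10 months, the robust fit and the GC and length offset were chosen after the data were seen, and the others before. RLE normalization kept all 32 counts within 1.5 times, DESeq2 17 of 30, limma on FPKM 14 of 26, no low-count filter 15 of 21, the fit of only the 2 groups 7 of 18, the replicate block 15 of 21, the robust fit 20 of 21 and the GC and length offset 6 of 7. The rank of the CAG length kept 2 of 3. With windows of 5 and 20 Mb the 9 tests near Htt did not pass, nor did they with 10 Mb, but with 0 to 3 calls near Htt at 2 and 10 months the tests of those ages decide little. For single named genes RLE kept the side of the threshold and the direction of 297 and lost 2 calls, DESeq2 kept 223, lost 31 and gained 3, limma on FPKM kept 188 and lost 111, and the robust fit kept 190 and lost 4. For the counts and genes below that moved the cause was not tested, though fits with fewer libraries have less power by construction. Depth and the low-count filter limited the genes tested to 15137, 15640 and 15689 at 2, 6 and 10 months.

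With an estimated inter-gene correlation the lists called went from 15, 14 and 21 to 0 for the slope at 2, 6 and 10 months, from 18, 17 and 17 to 0 for Q175 against Q20, from 8, 9 and 9 to 0 for Q20 against the wild type, and from 20, 17 and 14 to 2, 2 and 3 for sex.

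DESeq2 gave 169 and 15 genes for the slope at 2 and 10 months, 143 for Q175 at 2 months, 317 for Q111 at 6 months, 24 and 10 for Q140 at 2 and 10 months, 23 and 24 for Q80 at 2 and 10 months, 3 for Q92 at 2 months, and 1 and 5 for Q20 against the wild type at 2 and 10 months. For the sex difference in the slope it gave 172 and 132 at 6 and 10 months. Limma on log2 FPKM gave 528 and 1 for the slope at 6 and 10 months, 0 for Q175 at 10 months, 16 and 0 for Q111 at 6 and 10 months, 1, 489 and 0 for Q140 at 2, 6 and 10 months, 0 and 1 for Q80 at 2 and 10 months, 349 for Q92 at 10 months and 1 for Q20 against the wild type at 10 months.

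Without a low-count filter the slope gave 25 and 424 at 2 and 10 months, Q175 27 and 402, and Q92 1 and 394. Fits of only the 2 groups gave 94 and 0 for Q175 at 2 and 10 months, 0 and 0 for Q111 at 6 and 10 months, 1, 562 and 0 for Q140 at 2, 6 and 10 months, 1 for Q80 at 2 months, 2 and 176 for Q92 at 2 and 10 months and 0 for Q20 against the wild type at 10 months. With the replicate block the slope gave 41 and Q175 108 at 10 months, Q80 2 and 1 at 2 and 10 months, Q92 2 at 2 months and Q20 against the wild type 1 at 10 months. Deviations from group means correlated between same-sex libraries of different lines at a mean of 0.0823 for equal replicate numbers at 6 months, and −0.0271 for unequal ones. These means were −0.0133 and 0.00435 at 2 months and 0.00416 and −0.00109 at 10 months, so a pairing by replicate number stays open at 6 months only. The robust fit gave 1 for Q140 at 2 months, and the GC and length offset 2583 for Q20 against the wild type at 6 months.

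For the slope at 2, 6 and 10 months, females alone gave 1, 339 and 19 genes, males alone 11, 145 and 8, the fit without the Q175 libraries 1, 444 and 3, and that without the Q20 libraries 3, 60 and 723. In males alone the slope of Atf3 at 10 months turned to −0.14, and without the Q175 libraries those of Nrgn and Ttn turned to −0.083 and −0.32. The rank of the CAG length gave 619 at 6 months and the index set as a covariate 428, with the Q175 libraries F3 and M3 left out because their names carry no index number.

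Without the Q20 females F1, F3 and F4 the counts at 6 months were 21 for the slope, 149 for Q80, 505 for Q92, 1 for Q111, 167 for Q140 and 13 for Q175. Without the Q80 library M5, Q80 at 2 months gave 2. Without the Krt19-high libraries the slope at 10 months gave 170, Q92 18 and Q111 8, and Q111 at 6 months 85. Without the muscle or blood libraries the slope at 10 months gave 9 and Q175 3, and without these and the Krt19-high libraries the slope gave 6. In these fits for Q175 against Q20 Ftl2-ps turned to −0.083, Hba-a1 to −0.13, Nrgn to −0.20 and Ttn to −0.24, and for the slope Nrgn to −0.11 and Ttn to −0.32, or to −0.13 and −0.31 without the Krt19-high libraries as well. Without the Q20 female F1 of 10 months Q80 gave 1, Q140 0 and Q20 against the wild type 1. Leaving out 1 library of Q175 or Q20 at a time gave 19 (without the Q20 female F4) to 77 genes (without the Q175 female F2) at 2 months, 987 (Q20 female F1) to 2039 (Q20 male M4) at 6 months and 51 (Q175 female F3) to 365 (Q175 female F2) at 10 months.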

Other observations

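The tests on other splits of the samples were set before their results were seen, and the sets of libraries left out at 10 months were chosen after their levels were seen.

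Clock genes differed between the sexes. Of 20 circadian clock genes 14 were higher and 6 lower in females at 6 months, and 14 and 6 when adjusted over the list alone (camera adjusted p = 0.0193, and adjusted p = 0.521 with an estimated correlation). Arntl, which encodes BMAL1, was lower in females (−2.39 ± 0.27 at 2 months and −2.69 ± 0.25 at 6 months, SE), as was Clock (−1.15 ± 0.07, −1.39 ± 0.06 and −1.24 ± 0.10 at 2, 6 and 10 months), and Per3 was higher (1.54 ± 0.14, 2.18 ± 0.16 and 1.44 ± 0.16). The hour of tissue collection is not given in the sources used here. Genes of antigen presentation were higher in females, 12, 14 and 13 of 15 at 2, 6 and 10 months and as many when adjusted over the list alone, with the immunoproteasome subunit Psmb8 at 0.54 ± 0.05, 0.59 ± 0.06 and 0.64 ± 0.07. The camera adjusted p was 0.00156, 0.000511 and 5.55e-05, and adjusted p = 0.593, 0.597 and 0.554 with an estimated correlation.

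At 6 months genes of fatty acid oxidation moved both ways in Q175 against Q20. Of 25 PPARA targets and fatty acid oxidation genes 3 rose and 2 fell, as many as when adjusted over the list alone, with the receptor Ppara at −0.70 ± 0.14 (SE), the carnitine transferase Cpt1a at −0.39 ± 0.10 and the dehydrogenase Acadvl at 0.23 ± 0.06 (camera adjusted p = 0.0287, and adjusted p = 0.87 with an estimated correlation). Of 16 genes of huntingtin partners 1 rose, Rab11a (0.13 ± 0.04), and 2 fell, the transcriptional repressor Rest (−0.39 ± 0.09) and Hip1 (−0.62 ± 0.15), with 1 and 3 when adjusted over the list alone (camera adjusted p = 0.615).

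Other splits of the samples into groups of the same sizes were drawn, 100 for the slope and 40 for the other results. For the slope, counts as large were rare among the splits at 2 months (41 genes, highest of the other splits 267, with 3 of 100 as large) and 6 months (972, highest 36), and not at 10 months (93, highest 248, with 14 of 100). These splits moved single libraries between lines, so they cannot tell a trend on repeat length from other differences between lines. For Q175 against Q20 the real count ranked first of 40 splits at 2 months (47, highest other 4), 6 months (1699, highest 1202) and 10 months (197, highest 171). The same held for Q80 (1455, highest 26), Q92 (2814, highest 1175) and Q140 (936, highest 6) at 6 months, for Q92 (627, highest 15) and Q111 (174, highest 169) at 10 months, and for Q20 against the wild type at 6 months (5031, highest 1023). A first rank of 40, not adjusted over the results, leaves chance open where the margin is small, as for Q175 and Q111 at 10 months. It does not exclude that a few libraries carry a count. Leaving out 3 libraries took Q175 against Q20 to 13 genes at 6 months and 3 at 10 months. Chance cannot be excluded for Q111 at 6 months (194, highest 257), for Q80 at 2 months (15, highest 63, with 12 of 40) and 10 months (2, highest 9, with 21 of 40), for Q140 at 10 months (1, highest 14), or for Q20 against the wild type at 10 months (2, highest 3). At 2 months edgeR called 0 genes for Q92 (highest 2), Q111 (32), Q140 (1) and Q20 against the wild type (1), so that all 40 splits were as large; 1079, 903, 2011 and 500 genes had an unadjusted p below 0.05, and DESeq2 called 3, 0, 24 and 1. The sex difference in the slope at 2 months, also 0 in edgeR and DESeq2 with 803 genes at an unadjusted p below 0.05, had a split with 116 genes. Splits that called several times the real count, at 2 months for the slope and for Q80, may point to a structure of the samples that was not tested. For sex chance can be excluded at 2, 6 and 10 months (8714, 9529 and 8970 genes, highest 15, 5 and 23), and for age at 6 and 10 against 2 months (8323 and 3282, highest 901 and 99).

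For the lists called by camera at the preset correlation, the real count ranked first of 40 splits for sex at 2 months (20 lists, highest 19). This margin is too small to exclude chance. Chance cannot be excluded for sex at 6 months (17, highest 22, 10 of 40 as large) and 10 months (14, highest 24, 24 of 40). Nor can it for Q175 against Q20 at 2 months (18, highest 20, 3 of 40), 6 months (17, highest 23, 14 of 40) and 10 months (17, highest 25, 15 of 40). The same holds for Q20 against the wild type (8, 9 and 9 lists at 2, 6 and 10 months, highest 17, 24 and 20, with 32, 37 and 30 of 40). It holds for the slope too (15, 14 and 21 lists, highest 21, 26 and 25, with 22, 48 and 13 of 100).

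Leaving out libraries with RNA of other tissues at 10 months was compared with leaving out every other set of the same size from the same group. Without the Q175 libraries F3, F4 and M4 the count was 3, rank 1 of 56 sets, the others giving 11 to 858. Without the Q92 females F3 and F4 it was 8, rank 2 of 28, the others giving 3 to 1173. Without the Q111 libraries F4 and M3 it was 1, the others giving 1 to 354. Its rank of 3 of 28 counts ties, and no set gave fewer. These fits left out libraries of 1 line at a time, while the counts above without the Krt19-high libraries left out those of both lines.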
